A study of Mus musculus with 18 samples.

How the data were processed

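The series measured N6-methyladenosine (m6A), a common internal RNA mark, in BV-2 cells, an established mouse microglial cell line. Per the labels' protocols, RNA of each culture was separated with an antibody against m6A into a bound fraction (IP) and an unbound supernatant (Sup), a calibration RNA was added to both, and IP was labelled with Cy5 and Sup with Cy3. Both fractions of a sample share 1 of 9 two-colour Agilent arrays, so the 18 deposited samples are 9 arrays, 3 in each of 3 groups. No label says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these arrays, part of which may be technical.

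The deposited scanner tables hold spot intensity on a linear scale for both channels, written by Agilent Feature Extraction 11.0.1.1 per the file headers. Their processed intensity is background-subtracted and dye-normalized, per the file headers. The authors' series matrix holds log2 values. Each of its columns equalled log2 of the processed intensity of its own array and channel minus 1 constant per column, with a standard deviation of the difference of 0. Scale and direction are therefore known, and which probes set the constants is not given in the sources used here. The column medians ran from -3.40 to -2.01.

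Of 62976 spots on an array, 1439 were control spots and were left out. Tested probes were 60641 that carry only the identifier of the array design and 50 Agilent probes with an accession, the latter with 10 spots each. Through the RefSeq table of mouse genes (assembly GRCm38.p6), 45 of the 50 accessions matched a gene symbol; the files do not pair the other identifiers with genes. No coordinates are given, since the files and that table use different builds. Spots with an outlier flag were set to missing, and spots of 1 probe were averaged on the log2 scale. The m6A log ratio was log2 of IP over Sup, centred on each array's median over tested probes, and was tested for 36772 probes with both channels well above background on all 3 arrays of at least 1 group. RNA abundance was log2 of IP plus Sup minus each array's 75th percentile over non-control probes, tested for 48534 probes with at least 1 channel well above background on all 3 arrays of at least 1 group. After probes missing in a whole group were dropped, 36764 and 48526 were fitted. Changes are relative to that centre. With other scalings the median change of all probes moved by over 0.1: for abundance in LPS against control it was 0.09 as processed and -0.17 with calibration to the spike-in probes, and for the m6A log ratio 0.06 and -0.28. For abundance in LPS_EXO against control it was -0.11 as processed, -0.24 with that calibration and -0.34 in the series matrix.

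Group means were fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and Benjamini-Hochberg adjusted p under 0.05 was called. Every adjusted p in the text is limma's. On simulated data with the real spreads, a log2 change of 2 was recovered for 67% of changed probes in the m6A log ratio of LPS against control and for 58% in abundance, and a log2 change of 1 for 5% and 7%. For LPS_EXO against LPS the shares were 67% and 47% for a log2 change of 2, and 6% and 4% for 1. The simulated noise was independent between probes, with the spread pooled over the groups, so recovery in the real data may differ. Precision is limited by the number of arrays and by the pooled spread, which holds the gap between LPS_EXO arrays of different scan days. The share of tested probes well above background ran from 49.6% to 67.8% in IP and from 67.3% to 80.4% in Sup.

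The calibration probes were taken by their identifier: 102 probes on 306 spots, of which 19 were well above background in both channels on all 9 arrays and were used. For each array the median log2 of IP over Sup was set against their mean, with an exact two-sided permutation test of 3 against 3 arrays, whose smallest p is 0.1.

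The file headers place the 3 control arrays, the 3 LPS arrays and LPS_EXO replicate 1 in 1 scan of 1 slide, and LPS_EXO replicates 2 and 3 in 2 further scans on a second day. Within the first scan, row 1 held the controls and LPS replicate 1, and row 2 the other 3 arrays. LPS_EXO replicates 2 and 3 also lay in row 2, at positions 4 and 3. Replicate 3 had the position of replicate 1 and so lay on another slide. No slide identifier was read, so replicate 2, whose position no array of the first scan held, may lie on the first slide. Scan day was fitted as a block, which estimates LPS_EXO from replicate 1. Slide row as a block estimates LPS against control from LPS replicate 1 alone, LPS_EXO against LPS without that array, and LPS_EXO against control as the sum of both.

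Before the data were examined, 24 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took, per readout and for LPS against control and LPS_EXO against LPS, up to 6 risers and 6 fallers with a symbol that had an adjusted p under 0.05, a log2 change of at least 0.585 and no overlap of the groups, or the 4 genes of smallest p if none passed. It also took 2 members of each list by smallest p, and always Tnf, Il1b, Il6, Nos2, Ptgs2, Mettl3, Mettl14, Wtap, Fto and Alkbh5. Members of a list that did not pass could be left out of the text. None of those 10 has a probe with a symbol here. Only 6 lists had a member with a symbol, with 1 gene each, and the smallest list to be tested was 5 genes, so the planned tests of gene lists were not run.

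Alternatives were normexp background correction (offset 50, on median signals, since the tables used here have no mean signal), loess or quantile normalization, calibration to the spike-in probes, the series matrix, other background filters, each fraction alone, blocks, other variance settings and leaving out each array. The first scan alone, slide row as a block, the authors' constants, the simulated values for 1 LPS_EXO array, drawn with the spread within control and LPS, and the simulated overlap of lists of the observed lengths were added after the data were seen.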

Results

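BV-2 microglial cells were left untreated (control) or exposed to lipopolysaccharide (LPS, a bacterial cell wall component that activates microglia) at 1 µg/mL for 6 h. Another group (LPS_EXO) was incubated with exosomes from human umbilical cord mesenchymal stem cells for 24 h before the same LPS exposure. The labels give the exosomes as 1 µg/mL and 10 µl. No group received exosomes without LPS, so an effect on the LPS response cannot be told apart from one of exosomes alone. Each group had 3 arrays, and each array measured the m6A-bound (IP) and unbound (Sup) RNA of 1 sample. The question, as the series states it, is whether exosomes act on the inflammatory response through m6A. Among 39 genes with a symbol tested for abundance and 33 tested for the m6A log ratio there were no cytokines of the fixed lists and no enzymes of m6A. The cytokine Il2, outside those lists, was tested for abundance at a low level, with a mean of -4.44 in control. It had log2 differences of 0.37 for LPS against control (adjusted p = 0.502) and -0.18 for LPS_EXO against LPS (adjusted p = 0.597).

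In RNA abundance, the first principal component held 64.1% of the variance and separated LPS_EXO replicates 2 and 3, scanned on a second day, from the other 7 arrays. Correlations with those 7 ran from 0.853 to 0.889, against 0.929 to 0.994 among the 7. The second component held 21.0% and separated control from LPS.

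**Figure D1:**
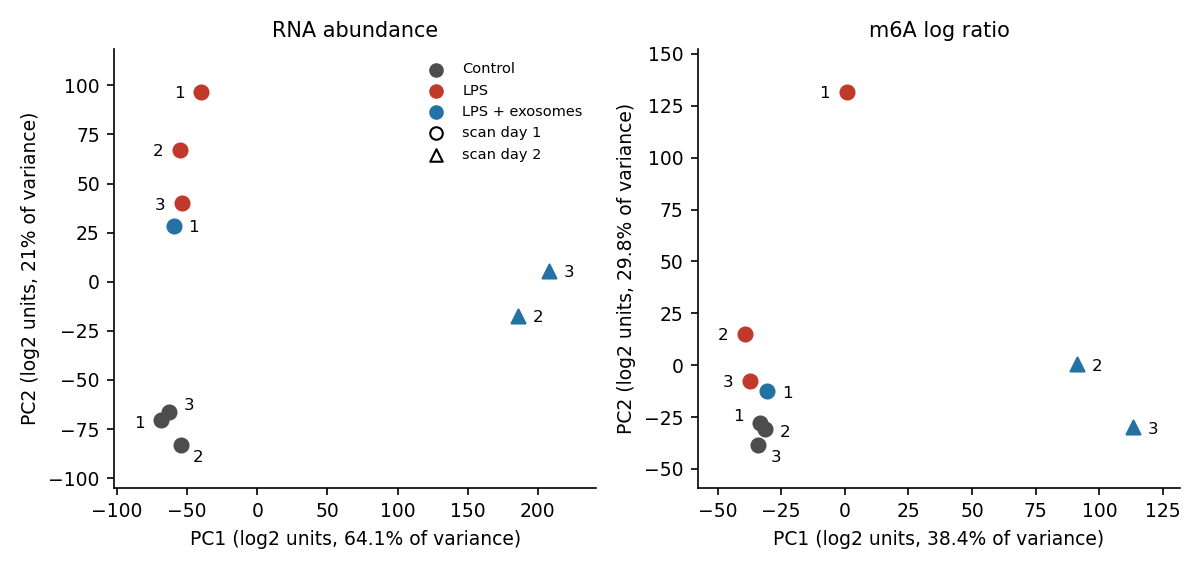
Principal components of RNA abundance (left, 47344 probes) and of the m6A log ratio (right, 35602 probes), both in log2 units; each point is 1 array, numbered by replicate, with circles for scan day 1 and triangles for scan day 2. The 2 arrays of scan day 2 lie at 186 and 208 on the first component of abundance, and the other 7 lie between -68.6 and -39.8.

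LPS lowered the abundance of Bambi, a transmembrane pseudoreceptor that dampens TGF-beta signalling: it was 13.1-fold lower than in control (log2 change -3.71, SE 0.27, adjusted p = 7.6e-05, n = 3 per group). E2f1, a transcription factor that drives entry into S phase, was 6.49-fold lower (log2 change -2.70, SE 0.23, adjusted p = 0.000178). Cpt1a, an enzyme needed for long-chain fatty acids to enter mitochondria for oxidation, was 3.61-fold lower (log2 change -1.85, SE 0.24, adjusted p = 0.00168). Dnajc11, a mitochondrial protein, and Hyal3, of the hyaluronidase family, were 2.01-fold and 1.99-fold lower (adjusted p = 0.0316 and 0.016). Carhsp1, an RNA-binding protein, was the only one of the 39 called higher, by 2.56-fold (log2 change 1.35, SE 0.27, adjusted p = 0.0147). Each of these 6 genes was separated from control in all 3 LPS arrays. In LPS, the IP signal of Bambi was not well above background on any array, and its log2 change was -3.56 in Sup alone. With normexp, whose offset compresses changes of dim probes, the log2 change of Bambi was -1.33, that of E2f1 -1.10 and that of Cpt1a -1.77, all still called, so the folds of Bambi and E2f1 and the order of these 3 genes depend on the background correction.

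Of the fixed lists, 6 had 1 gene with a symbol each. E2f1, the only measured member of the cell cycle list, fell. Gsdmd, the pore-forming executor of pyroptosis, had a log2 difference of 0.38 (SE 0.21, adjusted p = 0.404), Apoe, a lipid carrier, one of -0.27 (adjusted p = 0.697), Gpi1, a glycolytic enzyme, one of -0.10 (adjusted p = 0.852), and Atg3, of autophagy, one of 0.20 (adjusted p = 0.83). None of these 4 passed the test over all probes, and the sign turned for Atg3 with calibration to the spike-in probes (-0.078) and for Gpi1 in Sup alone (0.057). The probe of the myelin gene Mbp, a marker of another cell type, did not pass the background filter and was not fitted.

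Over all 48526 probes, 3336 were called between LPS and control, 1243 higher and 2093 lower. Of these, 2885 were well above background on every array of both groups; for the others the size of the change is not measured. Among the 2885, probe ASMM10EP3A112010003, whose gene the files do not name, had a log2 change of 10.30, and ASMM10EP3A100060384 one of -4.90. Groups did not overlap for 42.5% of probes, where chance gives 10% on average over splits of the arrays. Probes move together, so a single split can lie far from that average. The number called rested on the pooled spread, which includes the LPS_EXO arrays: within the first scan 10076 were called, with scan day as a block 8242, and without LPS_EXO replicate 1 it was 8411. Without control replicate 1, 2 or 3 it was 1551, 1429 and 1573, and without LPS replicate 1 or 2 it was 2101 and 1523. With calibration to the spike-in probes 800 were higher and 4057 lower, and with normexp 1608 and 1774. Bambi, E2f1 and Cpt1a passed in all 22 alternative fits. Carhsp1 lost its call without control replicate 1 or 3 (adjusted p = 0.078 and 0.0776), without LPS replicate 2 or 3 (0.0592 and 0.0526) and with calibration to the spike-in probes (0.0556), over a range of 0.00202 to 0.162. Dnajc11 lost it without control replicate 1, 2 or 3 (0.13, 0.161 and 0.0909), without LPS replicate 1 or 2 (0.115 and 0.141), in Sup or IP alone (0.116 and 0.0512) and with replicate number as a block, over a range of 0.00844 to 0.161. Hyal3 lost it without control replicate 1, 2 or 3 (0.0942, 0.0841 and 0.0647), without LPS replicate 2 (0.0912), in Sup alone (0.173) and with normexp (0.0765), over a range of 0.00161 to 0.173. Over the 22 alternative fits its log2 change ran from -1.36 to -0.24, so its fold also depends on the processing. That of Dnajc11 ran from -1.36 to -0.84 and that of Carhsp1 from 1.07 to 1.47. Slide row as a block sets LPS replicate 1 alone against control, with wider SE: Carhsp1 then had a log2 change of 1.12 (SE 0.38, adjusted p = 0.162), Dnajc11 of -1.29 (SE 0.32, adjusted p = 0.0612) and Hyal3 of -0.90 (SE 0.28, adjusted p = 0.135).

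**Figure D2:**
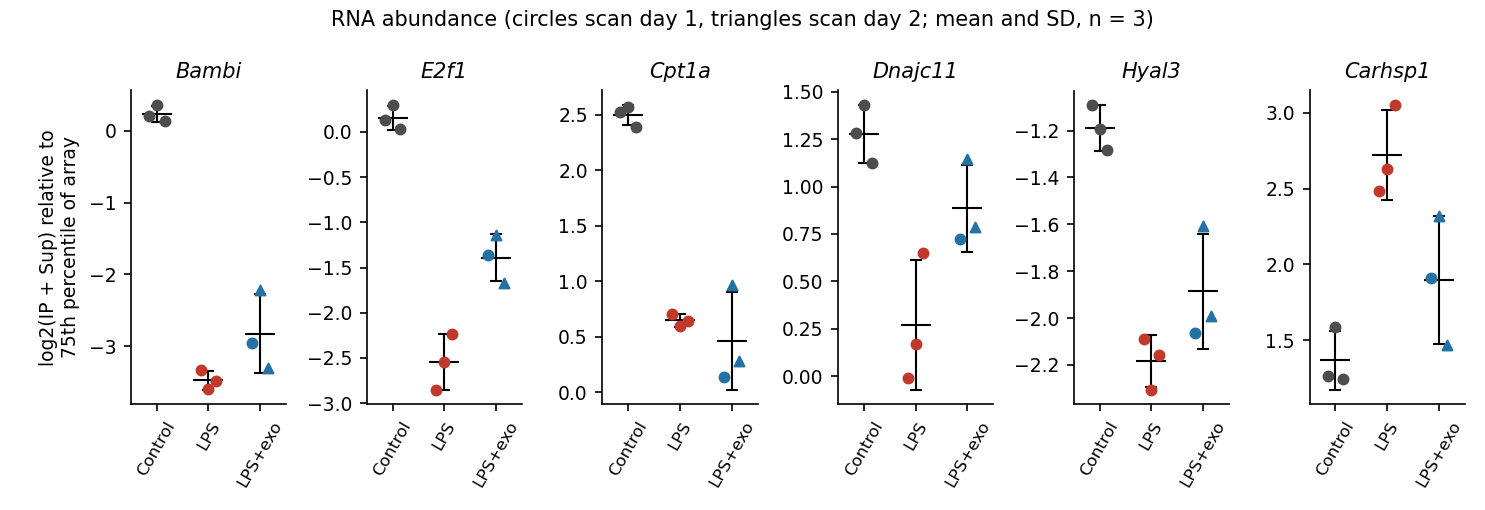
RNA abundance of the 6 genes that passed between LPS and control, as log2(IP + Sup) relative to the 75th percentile of the array; points are arrays (circles scan day 1, triangles scan day 2), and bars give the mean and SD of 3. Bambi lies at 0.24 in control, -3.47 in LPS and -2.82 in LPS_EXO, and the vertical axes differ between genes and do not start at 0.

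In the m6A log ratio, limma called 0 of 33 genes with a symbol between LPS and control with p adjusted over 36764 probes. Of the 33, 4 had an unadjusted p under 0.05, as had 4528 of all 36764 probes. With p adjusted over the 33 genes alone, 2 passed, Chgb and Acaa2. The 4 of smallest p were Chgb, Acaa2, E2f1 and Hyal3. Acaa2, an enzyme of mitochondrial fatty acid oxidation, had a log2 ratio of -2.04 ± 0.25 in control and -3.18 ± 0.07 in LPS (SD, n = 3; adjusted p = 0.0688). E2f1 stood at 0.29 ± 0.15 and -0.70 ± 0.87 (SD, n = 3; adjusted p = 0.338), with a difference of -0.50 without LPS replicate 1, and Hyal3 at 0.92 ± 0.13 and 0.32 ± 0.18 (SD, n = 3; adjusted p = 0.39). Chgb, a granin of secretory granules, had IP not well above background on any LPS array, so its ratio there is not a measured level (adjusted p = 0.0654); E2f1 had it so on LPS replicate 1. Acaa2 passed with normexp (adjusted p = 0.00982), loess (0.0405), calibration to the spike-in probes (0.0283) and probes above background on all 9 arrays (0.0413), over a range of 0.00982 to 0.365 across alternatives. Chgb passed with calibration to the spike-in probes (adjusted p = 0.0227) and without LPS replicate 3 (0.0246), over a range of 0.0107 to 0.98. Slide row as a block, which sets LPS replicate 1 alone against control, gave adjusted p of 0.0435 for Acaa2, 0.0107 for Chgb and 0.00598 for E2f1; the IP of Chgb and E2f1 was not well above background on that array.

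Across 36764 probes, 92 were called, 37 with a higher and 55 with a lower ratio, and 42 of them had both channels well above background on every array of both groups. Among the 42, ASMM10EP3A102351444 had a log2 change of 3.88 and ASMM10EP3A100115204 one of -2.96. Groups did not overlap for 24.8% of probes, where chance gives 10% on average over splits of the arrays. Since probes move together, a single split can lie far from that average. Of the 92, 66 were also called in abundance; both readouts come from the same IP and Sup signals and share their noise, so the 7.50 that independent lists would share is not the value expected without an effect. This count moved with the processing: normexp gave 1171 calls (111 higher, 1060 lower), loess 761 (143 and 618), calibration to the spike-in probes 373 (30 and 343), the series matrix 145 (21 and 124), probes above background on all 9 arrays 56, scan day as a block 178, and slide row as a block, which sets LPS replicate 1 alone against control, 4294 (1445 and 2849); within the first scan it was 111. Leaving out control replicate 1, 2 or 3 left 9, 20 and 19, leaving out LPS replicate 2 or 3 gave 32 and 174, and leaving out LPS_EXO replicate 1 gave 180. With replicate number as a block the count was 30 (15 higher, 15 lower).

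Between LPS_EXO and LPS, limma called 0 of 39 genes with a symbol in abundance with p adjusted over 48526 probes. Of the 39, 22 had an unadjusted p under 0.05, as had 17518 of all 48526 probes. With p adjusted over the 39 genes alone, 10 passed. E2f1 stood at -1.39 ± 0.26 in LPS_EXO and -2.55 ± 0.31 in LPS (SD, n = 3, adjusted p = 0.107), between the LPS and control levels on all 3 LPS_EXO arrays. Of the other genes called with LPS, Cpt1a had a log2 difference of -0.18, away from control (adjusted p = 0.574). Toward control, Carhsp1 had one of -0.82, Bambi of 0.65, Dnajc11 of 0.62 and Hyal3 of 0.30 (adjusted p = 0.108, 0.127, 0.112 and 0.276). Lhfp stood at 2.21 ± 0.55 against 1.06 ± 0.28, and Actb, a cytoskeletal actin, at 1.32 ± 1.18 against -0.64 ± 0.54 (SD, n = 3, adjusted p = 0.108 for both). The Actb probe was at 0.23 in control, against 7.52 for Gpi1, and whether it reports the main Actb transcript was not tested. H2-M2, a non-classical MHC class I gene, stood at 2.70 ± 1.08 against 4.39 ± 0.17 (SD, n = 3; adjusted p = 0.108). For Actb, LPS_EXO replicates 2 and 3 were at 1.52 and 2.38 and replicate 1, in the scan that holds the LPS arrays, at 0.06. With scan day as a block the log2 difference of Actb was 0.69, that of H2-M2 -0.57, that of Lhfp 0.53 and that of E2f1 1.18 (adjusted p = 1.00, 1.00, 0.972 and 0.368). Without LPS_EXO replicate 1, which leaves the arrays of the second scan day against LPS, these 4 genes passed (adjusted p = 0.000164 for Actb, 9.8e-05 for H2-M2, 0.000271 for Lhfp and 0.00213 for E2f1), as did Carhsp1 (0.0255) and Dnajc11 (0.0237).

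Over all probes, 62 were called between LPS_EXO and LPS, 17 higher and 45 lower. Of these, 46 were well above background on every array of both groups; among them ASMM10EP3A112170119 had a log2 change of 2.46 and ASMM10EP3A100023191 one of -2.78. Groups did not overlap for 21.6% of probes, where chance gives 10% on average over splits of the arrays. Probes move together, and the LPS_EXO arrays of the second scan day stand apart, so this excess does not measure an effect of exosomes. A block by scan day leaves LPS_EXO to replicate 1 alone, so its calls rest on the spread of other arrays. With scan day as a block 37 were called, 2 higher and 35 lower, and 20 of them were among the 62. The first scan alone, with 1 LPS_EXO array assumed to vary like the others, gave 31. Leaving out LPS_EXO replicate 1 gave 28965, leaving out LPS_EXO replicate 2 gave 11, and leaving out any other single array gave 0. No probe was called with slide row or replicate number as a block, with the series matrix or with only the 2 groups in the fit. Calibration to the spike-in probes gave 24 (9 higher, 15 lower), and normexp 47 (7 higher, 40 lower).

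The m6A log ratio gave 0 calls by limma between LPS_EXO and LPS among 36764 probes, with 7011 at an unadjusted p under 0.05; the series matrix gave 11 (9 higher, 2 lower). Of 33 genes with a symbol 10 had an unadjusted p under 0.05, and with p adjusted over these alone 1 passed, Bambi. The 4 genes of smallest p were Bambi, Chgb, Uhrf1bp1l and E2f1. E2f1 stood at 0.49 ± 0.30 against -0.70 ± 0.87 and Uhrf1bp1l at 2.51 ± 0.89 against 3.77 ± 0.40 (SD, n = 3; adjusted p = 0.201 for both); the difference of E2f1, 1.20, was 0.70 without LPS replicate 1, whose IP was not well above background. Bambi and Chgb had IP not well above background on any LPS array (adjusted p = 0.174 and 0.201), and the sign for Bambi turned with normexp (-0.057). With scan day as a block the adjusted p of all 4 was 0.984, with log2 differences of 0.88 for E2f1 and -0.23 for Uhrf1bp1l. Without LPS_EXO replicate 1, Bambi, Chgb and Uhrf1bp1l passed (adjusted p = 0.0162, 0.0435 and 0.0044). Leaving out LPS_EXO replicate 1 gave 6026 calls, and leaving out any other array gave 0. Within the first scan and with scan day as a block it was 0.

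Against control, LPS_EXO cells kept lower levels of Bambi, 8.36-fold (log2 change -3.06, SE 0.27, adjusted p = 0.000312), Cpt1a, 4.10-fold (log2 change -2.03, SE 0.24, adjusted p = 0.00145), and E2f1, 2.91-fold (log2 change -1.54, SE 0.23, adjusted p = 0.00519). Gamt, which makes creatine, was the fourth gene with a symbol that passed and is named after its values were seen (log2 change -1.43, adjusted p = 0.0215). Its log2 change was -0.71 with scan day as a block (adjusted p = 0.0998), and it also lost its call without control replicate 1, 2 or 3 (0.0986, 0.104 and 0.0811), without LPS_EXO replicate 2 or 3 (0.0756 and 0.0728), within the first scan (0.0766), with only the 2 groups in the fit (0.0833), in IP alone (0.0915) and with slide row as a block (0.313, log2 change -1.49), over a range of 2.18e-05 to 0.313. With scan day as a block, where LPS_EXO is replicate 1 alone, the log2 change was -3.19 for Bambi, -2.36 for Cpt1a and -1.51 for E2f1. Carhsp1 had a log2 difference of 0.53 (adjusted p = 0.18), Dnajc11 of -0.39 (adjusted p = 0.242) and Hyal3 of -0.70 (adjusted p = 0.0693, with 0.0144 without LPS_EXO replicate 1). Within the first scan and with scan day as a block LPS_EXO rests on 1 array, so its p-values there rest on the spread of other arrays. With slide row as a block, where LPS replicate 1 is the only link between control and LPS_EXO, the log2 change was -2.86 for Bambi, -2.00 for E2f1 and -1.95 for Cpt1a, and with the wider SE of 0.51, 0.39 and 0.45 they no longer passed (adjusted p = 0.0644, 0.081 and 0.121). E2f1 did not pass in IP alone (0.0817). With normexp the log2 change of Bambi was -1.34 and that of E2f1 -0.87.

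In all, 3141 probes were called, 1685 higher and 1456 lower, and 2547 of them were well above background on every array of both groups; with scan day as a block it was 1625, with slide row as a block, linked by LPS replicate 1 alone, 232, and with calibration to the spike-in probes 1066 higher and 1642 lower. Without LPS_EXO replicate 1 it was 28249, without replicate 2 or 3 1679 and 1584, without LPS replicate 2 it was 1781, and without control replicate 1, 2 or 3 it was 967, 954 and 959. LPS and LPS_EXO shared 876 lower probes (62.8 for independent lists) and 839 higher (43.2); simulated unchanged groups against the shared controls shared 0, since in the median simulation none were called. The most extreme probes of such groups, in lists of the observed lengths, shared 408 to 485 lower and 320 to 373 higher probes over 20 simulations, so part of the excess over independent lists may come from those controls. In the m6A log ratio 11 probes were called, and 3 of them had both channels well above background on every array of both groups, so for the others the size of the change is not measured. There were 6 higher and 5 lower calls (2 and 13 with calibration to the spike-in probes, 43 and 213 with normexp, 82 and 180 with loess, 2 and 4 with the series matrix, 7 and 12 with trend and robust variances, and 349 and 1529 with slide row as a block, linked by LPS replicate 1 alone). Without LPS replicate 1 it was 47, without LPS replicate 2 it was 3, without LPS_EXO replicate 1 it was 4645, without LPS_EXO replicate 2 or 3 it was 0, and without a control array 0 or 1. It was 0 within the first scan and with scan day as a block.

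Whether exosomes moved transcripts opposite to LPS was asked across probes, which are not independent replicates. In abundance the change with LPS and the change from LPS to LPS_EXO had r = -0.279, and arrays with no effect gave -0.50 because both changes share the LPS arrays. Their covariance was -0.148 against -0.0802 simulated. In the m6A log ratio r was -0.484, the simulated value -0.499, and the covariance -0.135 against -0.0668. These simulations used the spread pooled over the groups, which holds the gap between the LPS_EXO arrays; the variance of the LPS mean from the LPS arrays alone, which enters the covariance with a minus sign, was 0.0397 in abundance and 0.087 in the m6A log ratio. With slide row as a block, where the changes share no LPS array, r was -0.10 in abundance and 0.00899 in the m6A log ratio. With scan day as a block, which leaves LPS_EXO replicate 1, r was -0.531 in abundance and -0.632 in the m6A log ratio. Simulated values were -0.353 and -0.354. The covariances were -0.127 and -0.14 against -0.0262 and -0.0546 simulated. Those simulations pooled the spread of control and LPS. Their covariances were smaller in size than the variance of the LPS mean, 0.0397 and 0.087. They thus understate the opposition that noise alone gives, and the excess over them cannot be read as an effect of exosomes.

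The change of the m6A log ratio and that of abundance, which share the IP and Sup signals and thus their noise, had r = 0.487 (Spearman's rho 0.562) across 36764 probes for LPS against control. For LPS_EXO against LPS r was 0.0698 (Spearman's rho 0.091), and 0.532 with scan day as a block; it was -0.131 with normexp.

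Relative to the calibration probes, the median log2 of IP over Sup was 0.70 ± 0.15 in control, 0.36 ± 0.05 in LPS and 0.44 ± 0.13 in LPS_EXO (SD, n = 3). The difference of LPS from control was -0.34, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. LPS_EXO differed from LPS by 0.07 (exact permutation p = 0.5) and from control by -0.26 (exact permutation p = 0.2). Without LPS replicate 1, LPS_EXO replicate 1 or LPS_EXO replicate 3 the difference of LPS_EXO from LPS was 0.043, 0.0098 and 0.14. With the median of the calibration probes the 3 differences were -0.52, -0.14 and -0.67 (exact permutation p = 0.1, 0.6 and 0.1), with the authors' constants -0.21, 0.18 and -0.036 (exact permutation p = 0.5, 0.6 and 0.8), and before dye normalization the difference of LPS_EXO from LPS was -0.069, so that sign turned. In the first scan, LPS_EXO replicate 1 was at 0.56.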

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

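In this part, the tests of the calibration probes, of the departures from LPS and of the slide row were chosen after the results were seen; those of the bright probes were planned before theirs. A signal outside the tested probes stood above control: the array's custom probe CUST_9, whose target the files do not give, was higher by 1.34 on the log2 scale in LPS_EXO than in control. Its LPS_EXO mean was 6.34 ± 0.82, against 5.16 ± 0.41 in LPS and 4.99 ± 0.23 in control (SD, n = 3). Replicate 1, of the first scan, was at 5.42, below the highest array of that scan, 5.45, and replicates 2 and 3, of the second scan day, were at 6.57 and 7.02. Control probes named MM9NEGATIVE016 and MM9NEGATIVE017 were also higher in LPS_EXO than in control, by 1.29 and 1.18. Their LPS_EXO replicate 1 was at -2.55 and -2.82, and replicates 2 and 3 lay between -0.46 and 0.61. The other probes so named, where measured, differed by less.

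LPS_EXO replicates 2 and 3 stood apart from the other 7 arrays in abundance. Dim probes as the whole reason are argued against: among the brightest 11836 probes the highest correlation with the 7 arrays was 0.720, below the lowest among the 7, 0.836. A difference of scan, slide or hybridisation may account for it, since the calibration probes, which are not RNA of the cells, split alike, with a highest correlation of 0.874 against at least 0.979 among the 7. An effect of the exosomes stays open: the departures of replicate 1 from the LPS mean correlated by 0.0655 with those of replicates 2 and 3, and 1 array in the shared scan cannot exclude it. The second scan day holds LPS_EXO arrays alone, so exosomes and scan day cannot be told apart for these 2 arrays.

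LPS replicate 1 stood apart in the m6A log ratio, with a mean correlation of 0.871 with the other LPS arrays, and had the lowest share of probes above background in IP, 49.6%. Probes dim in IP as the whole reason are argued against: among the 8072 probes brightest in IP the correlation was 0.938, below the lowest of the other pairs of 1 group in that scan, 0.985. Over all probes that lowest value was 0.960. The bright probes were chosen by their mean over all arrays, so a weaker IP across the whole of LPS replicate 1 cannot be excluded. Its place in the slide row of the controls as the whole reason is also argued against: the controls lay in that row too, yet correlated by 0.941 to 0.954 with LPS replicates 2 and 3, and LPS replicate 1 by a mean of 0.835 with the controls. No biological explanation was tested, as the labels give these 3 arrays 1 treatment.

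With 10 splits of 6 arrays no share under 0.05 can be reached, so the following values do not settle whether chance groups the arrays. In abundance, LPS against control called 3336 probes and the highest other split 0 (1 of 10 splits gave as many, the real one). LPS_EXO against control called 3141 and the highest other split 2 (1 of 10). LPS_EXO against LPS called 62, and 2 of 10 splits gave as many. The highest, 1365, parted the row 2 arrays of the first scan from LPS replicate 1 and the arrays of the second scan day. It was several times the real count, which points to a structure of the arrays other than the groups. With slide row as a block 0 were called, and with scan day as a block 37. In the m6A log ratio, LPS against control called 92 and the highest other split 0 (1 of 10), and LPS_EXO against control 11 and 0 (1 of 10). LPS_EXO against LPS called 0, which 10 of 10 splits reach, and the split that called 1365 in abundance called 2423.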

How the results depend on the processing

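The first scan alone, slide row as a block and the authors' constants were tests chosen after the data were seen. Replicate numbers showed no clear pairing of the samples: deviations of arrays with the same number correlated from -0.251 to 0.137 in the m6A log ratio and from -0.265 to 0.313 in abundance, and 2 of 9 matched their own number best in each. The deviations of the LPS_EXO arrays hold the gap between scan days, so this check cannot exclude a pairing. With the replicate block, calls for LPS against control, LPS_EXO against LPS and LPS_EXO against control were 30, 0 and 0 in the m6A log ratio and 2511, 0 and 2143 in abundance; of the named genes, Dnajc11 between LPS and control changed its call (adjusted p = 0.065). In the same order, the m6A log ratio gave 1171, 0 and 256 calls with normexp, 761, 0 and 262 with loess, 373, 0 and 15 with spike-in calibration, 145, 11 and 6 with the series matrix, 178, 0 and 0 with scan day as a block, 4294, 0 and 1878 with slide row as a block, where both comparisons with control rest on LPS replicate 1, and 4002, 6463 and 5088 at an unadjusted p under 0.05 and 1.5-fold. It gave 56 for LPS against control with probes above background on all 9 arrays, and for LPS_EXO against control 19 with trend and robust variances and 0 in the first scan. Abundance gave 2152, 0 and 1447 with the series matrix, 8242, 37 and 1625 with scan day as a block, 10098, 0 and 1340 with only the 2 groups, 7778, 16323 and 15254 at an unadjusted p and 1.5-fold, 1815, 37 and 2014 in Sup alone, and 2743, 23 and 1832 in IP alone. Further counts for LPS_EXO against LPS were 24 with spike-in calibration, 31 in the first scan and 0 with slide row as a block; LPS against control in the first scan gave 10076, and LPS_EXO against control with slide row as a block 232. Leaving out 1 array gave 9 to 180, 0 to 6026 and 0 to 4645 calls in the m6A log ratio and 1429 to 8411, 0 to 28965 and 954 to 28249 in abundance. The block by scan day takes the gap between LPS_EXO arrays out of the pooled spread; the cause of the other shifts was not tested.

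The correlation of opposite changes in abundance was -0.531 with scan day as a block and -0.531 in the first scan. The simulated value for 1 LPS_EXO array was -0.353, which understates the noise of the LPS mean. With slide row as a block the correlation was -0.10 in abundance and 0.00899 in the m6A log ratio. The correlation of m6A with abundance for LPS against control was 0.364 with normexp and 0.637 with slide row as a block. For LPS_EXO against LPS it was -0.131 with normexp, -0.068 with probes above background on all 9 arrays, 0.532 with scan day as a block and 0.53 in the first scan. The calibrated IP over Sup differed by -0.52, -0.14 and -0.67 with the median of the calibration probes, by -0.21, 0.18 and -0.036 with the authors' constants, and by -0.069 for LPS_EXO against LPS before dye normalization. Between LPS_EXO and LPS with normexp, the sign turned for Bambi in the m6A log ratio (-0.057) and in abundance (-0.013) and for Hyal3 in abundance (-0.025); in Sup alone it turned for Hyal3 (-0.105) and Cpt1a (0.121). For LPS against control it turned for Gpi1 in Sup alone (0.057) and Atg3 with spike-in calibration (-0.078). Bambi, E2f1 and Cpt1a kept direction and call between LPS and control in all 22 alternative fits, with log2 changes from -4.09 to -1.33, -3.33 to -1.10 and -2.17 to -1.77. Low signal limits the m6A log ratio, since 25391 of 60691 probes were above background in both channels on all 9 arrays. Alternatives for the gene lists were not run, as no list was large enough.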

Other observations

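The test in this part was chosen after related results were seen. The LPS change of LPS_EXO replicate 1, the LPS_EXO array that shares a scan with the LPS arrays, looked smaller than that of the LPS arrays, and a hypothesis is that exosomes dampen the response to LPS. The change of each array from control was regressed across 47344 probes on the mean change of 2 LPS arrays, with the third held out. The slope of LPS_EXO replicate 1 lay below that of the held-out LPS array in 3 of the 3 choices: 0.757 against 1.05, 0.676 against 0.928 and 0.612 against 0.684. Replicates 2 and 3, of the second scan day, also lay below it in each choice, at 0.555 and 0.644, 0.593 and 0.705, and 0.498 and 0.644. The slopes of the LPS arrays themselves ran from 0.684 to 1.05 and overlap those of LPS_EXO, and only 1 LPS_EXO array shares their scan, so a dampened response, scan day and ordinary spread between arrays cannot be told apart.

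Among the control probes, the one named Rat-PGK1_3 had a mean of 0.34 ± 1.97 in LPS_EXO, 2.81 ± 0.28 in LPS and 2.49 ± 0.13 in control (SD, n = 3), and was at 2.61 in LPS_EXO replicate 1. Mouse-PGK1_3 had means of 7.28, 7.24 and 7.07 in the same order. The tested probes whose identifiers begin with ASMM10SM had a median m6A log ratio of -0.10 ± 0.21 in LPS_EXO, 0.17 ± 0.02 in LPS and 0.18 ± 0.01 in control (SD, n = 3); LPS_EXO replicate 1 was at 0.10, and replicates 2 and 3, of the second scan day, at -0.073 and -0.32.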
